A study of Mus musculus with 8 samples.

How the data were processed

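Gene expression was measured on Affymetrix gene arrays in NMuMG cells, a mouse mammary gland epithelial line. Per the labels, cells had been stably transfected with a control vector or with a vector for major satellite, the tandem repeat of mouse pericentromeric heterochromatin, and were untreated or treated with TGFbeta for 8 h. The 8 arrays fell into 4 groups of 2. The deposited values were log2 expression values per probeset on the scale of robust multi-array average (RMA). RMA and limma were named per the submitters' processing notes, and their versions, their roles and the genome build behind the probe annotation were not given in the sources used here. The table held 34760 probesets with 0 missing values and 0 identical pairs of arrays, and values ran from 2.98 to 14.75.

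The array titles carried 1 of 2 codes, each shared by 1 array of every group. The shared code was read as the mark of a day or batch, and the arrays were given replicate number 1 or 2 by it. Nothing in the labels said that replicates were separate cultures, so the p-values measure only the spread between these arrays. The number of arrays limits the precision. To check the pairing, each array's deviation from its group mean was correlated, across genes, with that of the arrays of the same number in the other groups. These correlations were 0.758 to 0.874, and genes are not independent replicates.

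Probesets were named from the platform's probe table, and symbols were brought up to date through Entrez identifiers with the RefSeq annotation of GRCm38.p6, which was used for names and, in 1 test of the closing section, for the chromosomes of genes. Of the 34760 probesets, 21640 had 1 gene symbol, 1321 had several and 11799 were not in the probe table. Of the symbols tested, 19855 were updated and 82 were kept from the probe table. For the 954 genes with more than 1 probeset, the probeset with the highest mean over the 8 arrays was used, which left 19937 genes. Probesets with several symbols or none were left out of the comparisons, because their signal cannot be given to 1 gene, and are described in the closing section. Positions of probesets on the genome were not used here.

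Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) on the deposited log2 values, with 1 mean per group over all 8 arrays and 4 residual degrees of freedom. The 5 comparisons were TGFbeta against untreated in each line, major satellite against control vector without and with TGFbeta, and the difference between the 2 TGFbeta responses. The average TGFbeta response of both lines was also fitted, and the average difference between vectors was added after the data had been seen. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 19937 genes of a comparison, and a gene passed at an adjusted p under 0.05. Errors are standard errors of the fitted log2 difference, and intervals are 95% confidence intervals. The model without the replicate number was chosen before the data were examined, as were the comparisons, the gene lists, the rule for named genes and the alternatives not described as added. Because the replicate number moved most counts, values from the same limma model with the replicate number as a further term (3 residual degrees of freedom) are given beside the results and called blocked.

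The named genes of each comparison followed 1 rule. They were the 8 passing genes with the largest rise and the 8 with the largest fall among those with the same sign in both replicate numbers, without predicted or uncharacterised loci and small RNA genes. To these were added up to 4 passing members of each gene list with the smallest p, and 8 genes fixed whatever their p. Of the 8 fixed genes, 6 were measured (Snai1, Zeb1, Cdh1, Fn1, Vim and Smad7) and 2 were not analysed here. Where fewer than 5 genes passed, all of them were named, and the 5 genes with the smallest p were given as values. Genes named outside this rule are described as chosen after their values were seen.

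The 21 gene lists covered TGFbeta/Smad immediate targets, BMP and Id genes, EMT (epithelial-mesenchymal transition) transcription factors, mesenchymal markers, epithelial junction and identity, collagens and matrix crosslinking, actin cytoskeleton and focal adhesion, DNA replication and G1/S, mitosis and G2/M, heterochromatin and pericentromere, and interferon and RNA sensing. They further covered p53 and DNA damage, the integrated stress and unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, Notch and Wnt targets, inflammatory cytokines and NF-kappaB, mammary luminal and milk genes, mammary basal and myoepithelial genes, fibroblast markers, and endothelial and immune markers. Each list was tested against all other genes with camera (two-sided, preset correlation 0.01), adjusted over the 21 lists of a comparison. Camera was repeated with an estimated correlation. That setting also replaces the degrees of freedom over all genes by the residual ones of the fit, 4 or, blocked, 3. It raised p even where the estimated correlation lay below 0.01 (cholesterol synthesis between untreated lines, correlation -0.0365, camera p = 0.0355 preset and 0.0862 estimated). A call lost in it thus cannot be put down to correlation between genes alone. Fry was run as a different test, of whether the genes of a list changed on balance in one direction, or in either direction, and it compares a list with no other genes. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. Blocked counts of list members are adjusted over all genes unless stated otherwise, also where they follow a count adjusted over the list alone. Overlap of the 2 sets of TGFbeta genes was tested with Fisher's exact test, two-sided. The relative size of the 2 responses was taken over the genes past the threshold in the average TGFbeta response, as the median difference of the responses, tested with camera, and as the slope through the origin by total least squares.

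The fit was tested on simulated data with 19937 genes, 200 of them changed by TGFbeta, and the same spread between replicate numbers. Without the replicate number it recovered 33% of the genes changed 2-fold and 84% of those changed 4-fold, with 0 false calls. With the replicate number it recovered 89% and 100%, with 2 false calls. Simulated slopes of 0.8 and 1 were returned as 0.801 and 1.01.

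The alternatives were the replicate number as a fixed or random term, median-centred arrays, quantile normalization of the 8 arrays again, all probesets of the table, the mean of a gene's probesets, and leaving out the dimmest 30% of genes. Further alternatives were a trended and robust variance, fits on the groups of 1 comparison alone, an adjusted p threshold of 0.1, a minimum change of 2-fold, other selections of genes for the size of the response, and leaving out each array in turn. The blocked fits without each array in turn and the test of the probesets outside the gene comparisons were added after the data had been seen. Leaving out an array leaves 1 array in its group, so genes called there can rest on that array alone.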

Results

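The data were log2 expression values from 8 arrays of total RNA of NMuMG cells, a mouse mammary epithelial line in which TGFbeta is known to induce an epithelial-mesenchymal transition. Cells with a control vector and cells with a major satellite vector were compared, each untreated or after 8 h of TGFbeta, with 2 arrays in each of the 4 groups. Array medians lay between 7.72 and 7.76 in the 4 arrays of replicate number 1 and between 7.88 and 7.92 in the 4 arrays of number 2. Across genes, arrays of the same number in different groups correlated at r = 0.983 to 0.998, and the 2 arrays of a group at r = 0.982 to 0.986. Of the variance across arrays, 49.9% lay on a first principal component that separated the replicate numbers, and 36.2% on a second that separated TGFbeta from untreated arrays. Changes are given as log2 differences ± standard error (SE), each from 2 arrays per group, with adjusted p from limma. Blocked values come from the limma model that also held the replicate number. Blocked counts of list members in brackets are adjusted over all genes, also where they follow a count adjusted over the list alone.

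**Figure D1:**
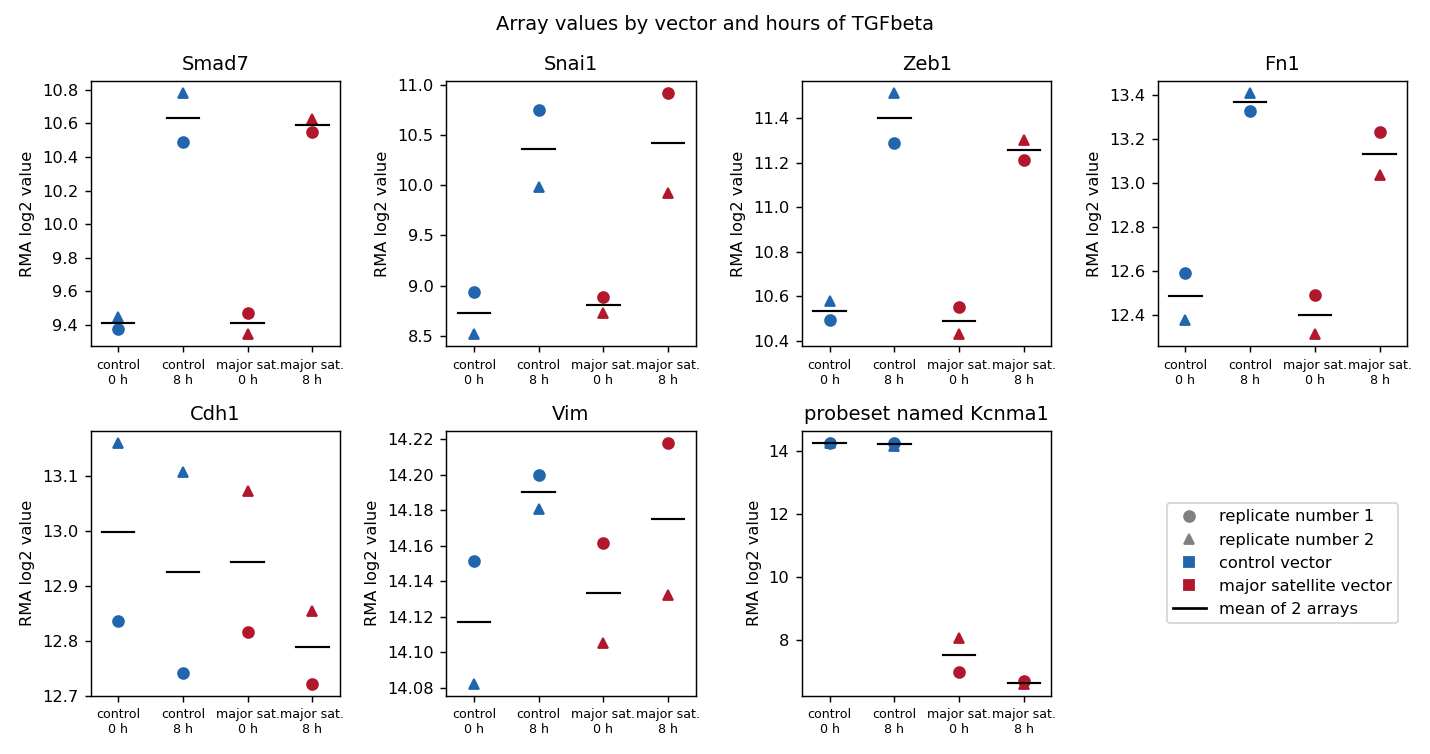
RMA log2 value of each array (vertical axis, 1 panel per gene) in the 4 groups, with circles for replicate number 1, triangles for number 2 and bars for the mean of 2 arrays. Smad7 lay 1.22 higher after TGFbeta in control vector cells and 1.18 higher in major satellite cells, while the probeset named Kcnma1 had group means of 14.24 and 14.19 in control vector cells and 7.52 and 6.65 in major satellite cells.

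The first comparison asked which transcripts changed within 8 h of TGFbeta in cells with the control vector. Prg4, which encodes the joint lubricant lubricin, rose by 5.02 ± 0.49 (adjusted p = 0.014). Has2, a hyaluronan synthase, rose by 3.08 ± 0.25 (adjusted p = 0.0108), and Thbs1, which encodes the matrix glycoprotein thrombospondin 1, by 2.72 ± 0.34 (adjusted p = 0.0243). Cxcl5, a neutrophil-attracting chemokine, changed by -3.19 ± 0.19 (adjusted p = 0.00834), and Stc1, which encodes the secreted glycoprotein stanniocalcin 1, by -2.61 ± 0.37 (adjusted p = 0.0357). The other 5 of the 8 largest rises were Ctsw (3.65), Adgra1 (3.29), Mab21l4 (2.75), Sdc3 (2.52), a cell-surface heparan sulfate proteoglycan, and Lect2 (2.51). The other 6 of the 8 largest falls were Ugt2b34 (-2.60), Cyp2s1 (-2.47), a cytochrome P450, Ly6g2 (-2.30), the axon guidance gene Sema3c (-2.04), the alcohol dehydrogenase Adh7 (-2.03) and Sorbs2 (-2.00). In all, 214 of 19937 genes passed, 141 higher and 73 lower, and 162 of them changed at least 2-fold. All 214 had the same sign in both replicate numbers, which calling on the same arrays nearly fixes.

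Among the fixed genes, Smad7, the feedback inhibitor of TGFbeta receptors, rose by 1.22 ± 0.14 (adjusted p = 0.0183) in control vector cells. Zeb1, a transcription factor that represses epithelial genes, rose by 0.87 ± 0.13 (adjusted p = 0.0401), and Fn1, which encodes fibronectin, by 0.88 ± 0.14 (adjusted p = 0.048). Snai1, a repressor of the E-cadherin gene, was 1.63 ± 0.38 higher and did not pass (adjusted p = 0.147), whereas its blocked adjusted p was 0.000325. Cdh1, which encodes E-cadherin, differed by -0.07 ± 0.19 (adjusted p = 1, blocked 0.698), and Vim, which encodes the intermediate filament vimentin, by 0.07 ± 0.11 (adjusted p = 1, blocked 0.663).

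Of the 23 measured TGFbeta/Smad immediate targets, 5 rose, 0 fell and 18 did not pass in control vector cells, and 15 rose when adjusted over the list alone (blocked 19 rose, 0 fell). Spsb1, an adaptor of a ubiquitin ligase, rose by 2.19 ± 0.20 (adjusted p = 0.0132), the small GTPase gene Rhob by 1.95 ± 0.13 (adjusted p = 0.00834) and the transcription factor gene Bhlhe40 by 1.77 ± 0.17 (adjusted p = 0.014). The list's median change was 0.89, with a camera adjusted p of 5.02e-19 and an adjusted p = 0.149 with an estimated correlation. Of 15 EMT transcription factors, 2 rose (Runx1, by 1.33 ± 0.13, and Zeb1), 1 fell (Twist2, -0.96 ± 0.15) and 12 did not pass. Adjusted over the list alone, 6 of them rose and 2 fell (blocked 10 rose, 2 fell). Their median change was 0.48 (camera adjusted p = 2.52e-05), with an adjusted p = 0.149 with an estimated correlation. Of 19 mesenchymal markers, 4 rose and 15 did not pass, with 6 rises when adjusted over the list alone (blocked 8 rose, 0 fell). Itga5, a fibronectin receptor subunit, rose by 2.11 ± 0.26, the matrix glycoprotein gene Tnc by 1.68 ± 0.18 and the adhesion molecule gene Ncam1 by 1.06 ± 0.14. Mesenchymal markers had a median change of 0.33, and 0.20 and 0.28 within replicate numbers 1 and 2 (camera adjusted p = 7.94e-07), and an adjusted p = 0.264 with an estimated correlation.

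Collagens and matrix crosslinking genes had 1 of 32 members that rose in control vector cells, Timp3, an inhibitor of metalloproteinases (1.92 ± 0.29, adjusted p = 0.0419). When adjusted over the list alone, 5 rose (blocked 14 rose, 1 fell). Their median change was 0.27 (camera adjusted p = 7.02e-06), with an adjusted p = 0.754 with an estimated correlation. None of 33 actin cytoskeleton and focal adhesion genes passed, and adjusted over the list alone 6 rose and 1 fell (blocked 12 rose, 2 fell). Their median change was 0.18 (camera adjusted p = 7.37e-05), with an adjusted p = 0.765 with an estimated correlation. DNA replication and G1/S genes had a median change of -0.67 (camera adjusted p = 9.97e-11), with an adjusted p = 0.754 with an estimated correlation. Of these 30 genes, Ccne2, which encodes the S-phase cyclin E2, fell by 1.35 ± 0.21 (adjusted p = 0.0473) and 29 did not pass. It was also the 1 that fell when adjusted over the list alone. Blocked, 0 rose and 23 fell adjusted over all genes, and 0 rose and 30 fell adjusted over the list alone. None of 31 mitosis and G2/M genes passed, also when adjusted over the list alone (blocked 0 rose, 11 fell). Their median change was -0.32 (camera adjusted p = 6.28e-06, and an adjusted p = 0.754 with an estimated correlation), and -0.15 and -0.50 within replicate numbers 1 and 2. Of 12 BMP and Id genes, Id2, an inhibitor of helix-loop-helix factors, fell by 1.98 ± 0.19 (adjusted p = 0.014) and 11 did not pass. When adjusted over the list alone, 2 fell (blocked 1 rose, 4 fell). The BMP and Id list had a median change of -0.06 (-0.20 and -0.01 within the replicate numbers) and a mean of -0.33 (camera adjusted p = 0.0316, blocked 0.12), with an adjusted p = 0.754 with an estimated correlation. In the 23 Notch and Wnt targets, the Notch ligand gene Jag1 rose by 1.55 ± 0.19, the receptor gene Notch1 fell by 0.98 ± 0.14 and 21 did not pass. Of these targets, 3 rose and 1 fell adjusted over the list alone (blocked 6 rose, 2 fell). That list's median change was 0.16, and 0.08 and 0.25 within the replicate numbers (camera adjusted p = 0.0284), with an adjusted p = 0.765 with an estimated correlation.

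For the other 12 lists, camera called no shift in control vector cells, with adjusted p from 0.509 to 0.761. Of 36 epithelial junction and identity genes, Cldn4, a tight junction claudin, rose by 2.26 ± 0.14 (adjusted p = 0.00834) and 35 did not pass. The list had 2 rises and 1 fall adjusted over the list alone (blocked 5 rose, 5 fell) and a median change of 0.00. Of 26 inflammatory cytokine and NF-kappaB genes, Il11, which encodes interleukin 11, rose by 1.92 ± 0.19 and Cxcl5 fell. This list had 1 rise and 4 falls adjusted over the list alone (blocked 4 rose, 6 fell), a median of 0.03 and a mean of -0.23. Of 22 glycolysis and hypoxia genes, Pfkfb4 (2.02 ± 0.23) and Pfkfb3 (1.15 ± 0.18), both regulators of glycolysis, rose and Egln3, a prolyl hydroxylase acting on HIF, fell by 1.96 ± 0.26. That list had 3 rises and 1 fall adjusted over the list alone (blocked 5 rose, 1 fell), a median of -0.05 and a mean of 0.12. Of 31 interferon and RNA sensing genes, Oasl2 rose by 1.62 ± 0.16 and Ifit3 fell by 1.45 ± 0.20, both known as interferon-induced. There 1 rose and 2 fell adjusted over the list alone (blocked 2 rose, 3 fell). Of 21 p53 and DNA damage genes, Gadd45a rose by 2.41 ± 0.24 (adjusted over the list alone also 1, blocked 1 rose, 3 fell). Of 26 integrated stress and unfolded protein response genes, Xbp1 rose by 0.72 ± 0.11 (adjusted over the list alone 1 rose, 1 fell, blocked 4 rose, 5 fell). Heterochromatin and pericentromere genes had 0 of 32 passing (blocked 3 rose, 6 fell), and cholesterol synthesis 0 of 17 (blocked 1 rose, 1 fell), both also 0 when adjusted over the list alone. Mammary luminal and milk genes had 0 of 15 passing, also 0 adjusted over the list alone (blocked 1 rose, 1 fell). Mammary basal and myoepithelial genes had 0 of 15 passing, with 1 rise and 1 fall adjusted over the list alone (blocked 2 rose, 1 fell). Among markers of other cell types, 1 of 13 fibroblast markers fell (Twist2, adjusted over the list alone 1 rose, 1 fell, blocked 2 rose, 2 fell). Of 15 endothelial and immune markers, 0 passed (adjusted over the list alone 0, blocked 1 rose, 1 fell).

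With the replicate number in the model, 2901 genes passed in control vector cells, 1380 higher and 1521 lower, and these held all 214. Leaving out 1 of the 8 arrays left 0 or 1 genes when it was a control vector array and 81 to 89 when it was a major satellite array, and 1202 to 3161 genes in the blocked fits.

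**Figure D2:**
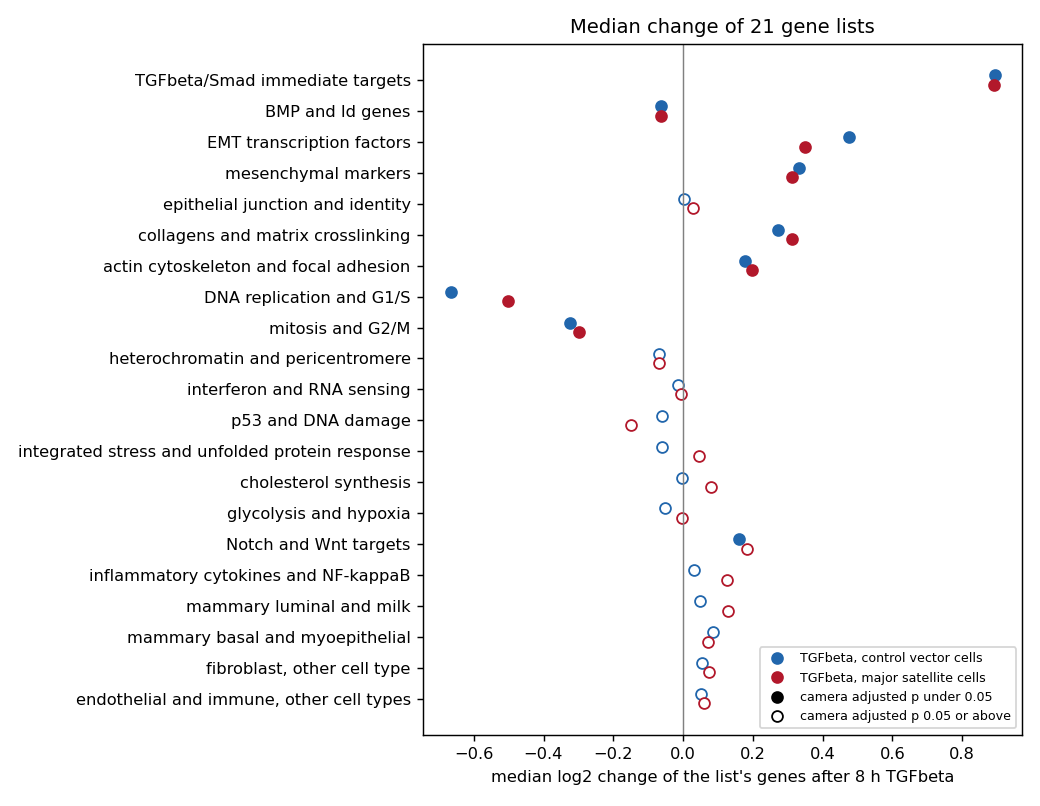
Median log2 change after 8 h of TGFbeta (horizontal axis) of the measured genes of each of the 21 lists, in control vector cells (blue) and major satellite cells (red), filled where the camera adjusted p was under 0.05. TGFbeta/Smad immediate targets had medians of 0.89 in both lines, and DNA replication and G1/S genes -0.67 and -0.50.

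The same question was asked of the major satellite cells. There, Prg4 rose by 4.76 ± 0.49 (adjusted p = 0.019), Has2 by 3.29 ± 0.25 (adjusted p = 0.00959) and Thbs1 by 2.56 ± 0.34 (adjusted p = 0.0328). Cxcl5 changed by -3.21 ± 0.19 (adjusted p = 0.00891) and Stc1 by -2.54 ± 0.37 (adjusted p = 0.0413). The other 5 of the 8 largest rises were Ctsw (3.72), Adgra1 (3.04), Mab21l4 (2.76), the folate enzyme gene Aldh1l1 (2.71) and Lect2 (2.51). The other 6 of the 8 largest falls were Cyp2s1 (-2.63), Ugt2b34 (-2.62), the metalloproteinase gene Mep1a (-2.30), the thyroid hormone deiodinase gene Dio3 (-2.13), Akr1c14 (-2.11) and Ly6g2 (-2.03). In all, 218 genes passed, 136 higher and 82 lower, and 156 of them changed at least 2-fold. All 218 had the same sign in both replicate numbers, which calling on the same arrays again nearly fixes. Smad7 rose by 1.18 ± 0.14 (adjusted p = 0.0243). Zeb1 (0.77 ± 0.13, adjusted p = 0.0546, blocked 0.00101) and Fn1 (0.73 ± 0.14, adjusted p = 0.0857, blocked 0.00123) did not pass without the replicate number. Nor did Snai1 (1.61 ± 0.38, adjusted p = 0.146, blocked 0.000366). Cdh1 differed by -0.16 ± 0.19 (adjusted p = 0.974, blocked 0.295) and Vim by 0.04 ± 0.11 (adjusted p = 0.992, blocked 0.784).

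TGFbeta/Smad immediate targets had 5 of 23 members that rose in major satellite cells, 14 adjusted over the list alone (blocked 17 rose, 0 fell). Among them were Spsb1 (1.95 ± 0.20), Bhlhe40 (1.85 ± 0.17) and Rhob (1.46 ± 0.13). Their median change was 0.89 (camera adjusted p = 1.09e-15), with an adjusted p = 0.286 with an estimated correlation. Of 15 EMT transcription factors, Runx1 rose by 1.12 ± 0.13, Twist2 fell by 0.98 ± 0.15 and 13 did not pass. With p adjusted over the list alone, 6 rose and 1 fell (blocked 8 rose, 1 fell). Their median of 0.35 had a camera adjusted p of 0.000722 and an adjusted p = 0.286 with an estimated correlation. Mesenchymal markers had 3 rises among 19, Itga5 (2.16 ± 0.26), Tnc (1.36 ± 0.18) and Ncam1 (1.05 ± 0.14), and 5 adjusted over the list alone (blocked 8 rose, 0 fell). Their median was 0.31, and 0.19 and 0.31 within the replicate numbers (camera adjusted p = 5.14e-06), with an adjusted p = 0.323 with an estimated correlation. Of 12 BMP and Id genes, Id2 fell by 1.80 ± 0.19 (adjusted p = 0.02) and Bmp4, which encodes a bone morphogenetic protein, by 1.32 ± 0.20 (adjusted p = 0.0431). These 2 were also the falls adjusted over the list alone (blocked 1 rose, 4 fell). The list's median was -0.06 and its mean -0.36 (camera adjusted p = 0.0156), with an adjusted p = 0.698 with an estimated correlation.

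None of the 32 collagens and matrix crosslinking genes passed in major satellite cells, and 7 rose adjusted over the list alone (blocked 16 rose, 1 fell). Their median was 0.31 (camera adjusted p = 3.52e-05, and an adjusted p = 0.736 with an estimated correlation). Actin cytoskeleton and focal adhesion genes had 0 of 33 passing, and 7 rises and 1 fall adjusted over the list alone (blocked 12 rose, 2 fell). The median of that list was 0.20 (camera adjusted p = 0.000722, and an adjusted p = 0.846 with an estimated correlation). DNA replication and G1/S genes had 0 of 30 passing, and 1 fall adjusted over the list alone (blocked 0 rose, 22 fell). Replication genes had a median of -0.50 (camera adjusted p = 1.59e-08, and an adjusted p = 0.698 with an estimated correlation). Mitosis and G2/M genes had 0 of 31 passing, also adjusted over the list alone (blocked 0 rose, 9 fell). Mitosis genes had a median of -0.30 (camera adjusted p = 8.87e-06, and an adjusted p = 0.698 with an estimated correlation), and -0.18 and -0.42 within the replicate numbers. The other 13 lists had camera adjusted p from 0.0735 to 0.972. Notch and Wnt targets, with 23 members, had 1 rise (Jag1, 1.53 ± 0.19) and 1 fall (Notch1, -1.25 ± 0.14), and 5 rises and 1 fall adjusted over the list alone (blocked 6 rose, 2 fell). They had a camera adjusted p of 0.0735 (blocked 0.0455), and an adjusted p = 0.846 with an estimated correlation (blocked 0.517).

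Among epithelial junction and identity genes, Cldn4 rose by 2.25 ± 0.14 in major satellite cells and 35 of 36 did not pass, with 1 rise adjusted over the list alone (blocked 6 rose, 7 fell). The test's direction for that list (down) differed from that of the median (0.03) and the mean (0.04). Il11 rose by 1.67 ± 0.19 and Cxcl5 fell among the 26 inflammatory cytokine and NF-kappaB genes. That list had 1 rise and 3 falls adjusted over the list alone (blocked 6 rose, 7 fell), a median of 0.12 and a mean of -0.17. Pfkfb4 rose by 2.18 ± 0.23 and Egln3 fell by 1.97 ± 0.26 among the 22 glycolysis and hypoxia genes, with 3 rises and 1 fall adjusted over the list alone (blocked 6 rose, 1 fell), a median of 0.00 and a mean of 0.17. Oasl2 rose by 1.45 ± 0.16 as 1 of 31 interferon and RNA sensing genes (adjusted over the list alone 1 rose, 1 fell, blocked 2 rose, 4 fell). Gadd45a rose by 2.26 ± 0.24 as 1 of 21 p53 and DNA damage genes (adjusted over the list alone 1, blocked 2 rose, 4 fell). Xbp1 rose by 0.80 ± 0.11 as 1 of 26 integrated stress and unfolded protein response genes (adjusted over the list alone 1 rose, 1 fell, blocked 4 rose, 6 fell), a list with a median of 0.05 and a mean of -0.04. Heterochromatin and pericentromere genes had 0 of 32 passing, 0 adjusted over the list alone (blocked 3 rose, 5 fell). Cholesterol synthesis genes had 0 of 17 (0 adjusted over the list alone, blocked 2 rose, 2 fell), with a test direction (down) unlike their median of 0.08, and mammary luminal and milk genes 0 of 15 (0 adjusted over the list alone, blocked 0). Mammary basal and myoepithelial genes had 0 of 15 passing (adjusted over the list alone 1 rose, 1 fell, blocked 2 rose, 1 fell), and endothelial and immune markers 0 of 15 (0 adjusted over the list alone, blocked 0 rose, 1 fell). Fibroblast markers had 1 fall, of Twist2 (adjusted over the list alone 1 rose, 1 fell, blocked 2 rose, 1 fell). With the replicate number in the model, 3044 genes passed in major satellite cells, 1374 higher and 1670 lower, and these held all 218. Leaving out 1 of the 8 arrays left 0 or 1 genes when it was a major satellite array and 63 to 82 when it was a control vector array, and 1228 to 3020 in the blocked fits.

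The next comparison asked whether major satellite changed the response to TGFbeta, as the difference between the response in major satellite cells and that in control vector cells. Smad7 had a difference of -0.04 (95% confidence interval -0.50 to 0.42), Zeb1 of -0.10 (-0.53 to 0.33) and Fn1 of -0.15 (-0.62 to 0.32). For Snai1 the difference was -0.02 (-1.32 to 1.28, blocked -0.57 to 0.53), for Cdh1 -0.08 (-0.71 to 0.55) and for Vim -0.03 (-0.39 to 0.33). In limma, 0 of 19937 genes passed with or without the replicate number. At an unadjusted p under 0.05 there were 44 genes, and 658 in the blocked fit, where 997 were expected by chance. The fit without the replicate number leaves the difference between numbers in its residual spread (median SE 0.237, blocked 0.136). Its p-values are therefore too large. A count below chance is no sign that the 2 responses were alike. The 5 genes with the smallest p were Ly6f (-0.84 ± 0.20), Cypt2 (0.96 ± 0.27), Tuba3b (-0.69 ± 0.20), Cep63, a centrosomal gene (-0.64 ± 0.18), and Ect2l (0.53 ± 0.16). Each had an adjusted p of 1, and the blocked adjusted p was 0.399 for Cypt2 and 0.999 for the others. None of the 21 lists passed (smallest camera adjusted p 0.795, blocked 0.194), and TGFbeta/Smad immediate targets had a median difference of -0.06 (-0.02 and -0.12 within replicate numbers 1 and 2). A p that misses the threshold does not show that the 2 responses were alike. The blocked fit without replicate 1 of the TGFbeta-treated major satellite cells called some genes. It left 1 array in that group, so these calls rest on that array and cannot show that the responses differed. Without any 1 of the other 7 arrays, 1 to 5 lists passed for the difference of responses. These list fits held no replicate number, and leaving out 1 array made the numbers unequal between the groups. A list that differs between numbers, such as DNA replication and G1/S (median -0.64, number 2 minus 1), can pass for that reason. These list calls therefore cannot show that the responses differed. With all arrays and an estimated correlation, each list had a camera adjusted p of 0.986.

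The genes that passed in the 2 lines overlapped. Of the 141 genes that rose in control vector cells and the 136 that rose in major satellite cells, 114 were shared, where 0.962 were expected (Fisher's exact test, p = 2.07e-250). Of the 73 and 82 that fell, 58 were shared, where 0.3 were expected (Fisher's exact test, p = 4.95e-136), and 0 genes passed in opposite directions without the replicate number. Has2, Prg4, Cxcl5, Smad7, Id2 and Cldn4 were among the named genes past the threshold in both lines. Across all genes, the 2 responses correlated at r = 0.883. Genes are not independent replicates, and both sets of calls used the same estimate of each gene's spread. The Fisher p-values and the r therefore cannot be read as if genes were separate samples. Within replicate numbers 1 and 2 the r was 0.833 and 0.778, and between lines of different numbers it was 0.718 and 0.812. The blocked fits shared 2229 genes, and 1 gene passed them in opposite directions, Cypt2 (-0.53 in control vector and 0.43 in major satellite cells), whose difference of responses did not pass (blocked adjusted p = 0.399). Without any 1 of the 8 arrays the fits without the replicate number shared 0 or 1.

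**Figure D3:**
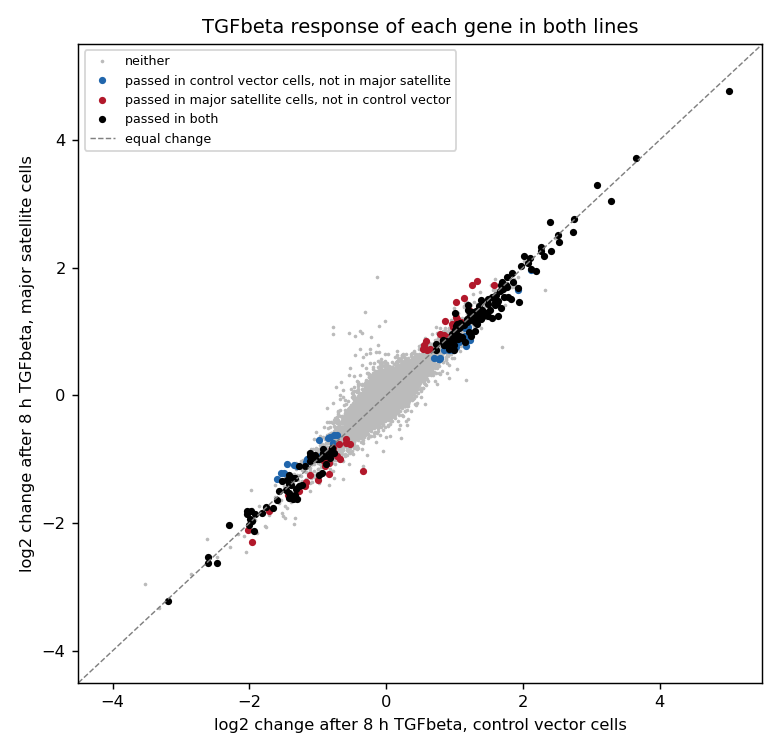
Log2 change of each of 19937 genes after 8 h of TGFbeta in control vector cells (horizontal axis) and major satellite cells (vertical axis), coloured by the line in which the gene passed, with a dashed line of equal change. The 172 genes that passed in both lines (114 higher, 58 lower) lie near the dashed line, and the slope over the 962 genes of the average response was 0.994.

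Averaged over both lines, TGFbeta changed 962 genes, 513 higher and 449 lower (blocked 4841, 2229 higher and 2612 lower). The 513 genes that rose had a median change of 0.88 in control vector cells and 0.82 in major satellite cells, with a median difference of -0.05 (-0.03 and -0.07 within replicate numbers 1 and 2). The 449 that fell had median changes of -0.76 and -0.81, with a median difference of -0.04 (-0.05 and -0.03 within the numbers). Camera gave p = 3.76e-05 for the genes that rose and p = 0.000636 for those that fell, and p = 0.181 and p = 0.43 with an estimated correlation. For the 2229 and 2612 genes selected in the blocked fit the differences were -0.03 (-0.02 and -0.04 within the numbers) and -0.03 (-0.04 and -0.02), with camera p = 0.0131 and p = 0.0107, with an estimated correlation p = 0.166 and p = 0.583. Over both sets the slope of the major satellite response on the control response was 0.994 (blocked selection 1.002), and 1.001 and 0.986 within the numbers. Leaving out 1 array gave counts of 359 to 638 (blocked 3498 to 4860) and slopes of 0.887 to 1.09. It turned the difference of the genes that rose to 0.05 without replicate 1 of the untreated major satellite cells. The difference of the genes that fell turned to 0.10 without replicate 1 of untreated control cells, to 0.11 without replicate 1 of TGFbeta-treated control cells, and to 0.03 without replicate 2 of TGFbeta-treated major satellite cells.

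The last comparisons asked which transcripts differed between major satellite and control vector cells. Without TGFbeta, 1 of 19937 genes passed, at the probeset named Kcnma1 (a potassium channel gene) in the probe table. It differed by -6.72 ± 0.32 (95% confidence interval -7.49 to -5.96, adjusted p = 0.0058, blocked 1.11e-05), and by -7.27 and -6.18 within replicate numbers 1 and 2. Its mean was 14.24 in control vector cells, where the highest values of the 2 arrays were 14.73 and 14.64, and 7.52 in major satellite cells. Array signal is compressed near the top of the range and near background, and detection was not analysed here, so the differences and intervals of this probeset hold for array values and not for the fold in transcript. The other probeset of Kcnma1 had means of 5.64 in control vector and 5.68 in major satellite cells over 4 arrays each. It lay near the floor in both (percentiles 9.65 and 10.1 of gene means), so it could hardly fall and cannot show whether the gene fell. In control vector cells it did not share the high value of the probeset used (mean 14.22 over 4 arrays). The probeset used lists 0 of the RefSeq transcripts of Kcnma1, and its value is given for the probeset. The fixed genes differed by 0.08 (Snai1), -0.04 (Zeb1), -0.05 (Cdh1), -0.08 (Fn1), 0.02 (Vim) and 0.00 (Smad7), each with an adjusted p of 1. Gm7982, Spopfm2, Tmem92 and BC147527 had the next smallest p. Gm7982, a predicted gene read from 1 of its 7 probesets, differed by -2.85 ± 0.27 (adjusted p = 0.259, blocked 0.00329) and Spopfm2 by -1.67 ± 0.24 (adjusted p = 1, blocked 0.0313). Tmem92 differed by -1.19 ± 0.21 (adjusted p = 1, blocked 0.00912) and BC147527 by -1.11 ± 0.21 (adjusted p = 1, blocked 0.101). The blocked fit passed 6 genes, all lower, of which 4 were the probeset named Kcnma1, Gm7982, Spopfm2 and Tmem92. The others were Zfp352 (-2.13, blocked adjusted p = 0.0432) and Pramel20 (-1.58, blocked adjusted p = 0.0481), both named after their values were seen. At an unadjusted p under 0.05 limma gave 86 genes, and 654 blocked, where 997 were expected by chance. No list passed camera (smallest adjusted p 0.336), and heterochromatin and pericentromere genes had a median difference of -0.01, which turned sign between replicate numbers 1 (0.01) and 2 (-0.06). Leaving out 1 array gave 0 genes without either untreated control array or either TGFbeta-treated major satellite array and 1 gene otherwise (blocked 2 to 9), and list counts of 1 to 7 without an untreated array.

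With TGFbeta, the probeset named Kcnma1 differed by -7.55 ± 0.32 (adjusted p = 0.00275, blocked 3.96e-06), with means of 14.19 and 6.65, and was again the 1 gene that passed. Snai1 differed by 0.06, Zeb1 by -0.14, Cdh1 by -0.14, Fn1 by -0.23, Vim by -0.02 and Smad7 by -0.05 between the TGFbeta-treated lines, each with an adjusted p of 1. The next smallest p belonged to Gm7982 (-2.66 ± 0.27, adjusted p = 0.398, blocked 0.00597), Spopfm2 (-1.92 ± 0.24, adjusted p = 0.951, blocked 0.00979), Tmem92 (-1.21 ± 0.21, adjusted p = 1, blocked 0.00822) and Tcstv3 (-0.73 ± 0.13, adjusted p = 1, blocked 0.137). The blocked fit passed 6 genes, all lower, and besides the first 4 these were Zfp352 (-2.55, blocked adjusted p = 0.00982) and Usp17ld (-1.01, blocked adjusted p = 0.0374), both named after their values were seen. Unadjusted p was under 0.05 for 85 genes (blocked 1298), where 997 were expected by chance, so only the blocked count exceeded it. TGFbeta/Smad immediate targets had a median difference of -0.09 (-0.02 and -0.16 within replicate numbers 1 and 2). Without the replicate number 0 of 23 members passed, also adjusted over the list alone. Blocked, 0 passed adjusted over all genes, and 1 was lower adjusted over the list alone. The list's camera adjusted p was 0.0123 (blocked 0.00408), and 0.95 with an estimated correlation (blocked 0.954). Blocked, camera also passed DNA replication and G1/S (median 0.12, adjusted p = 0.00361), cholesterol synthesis (0.10, and 0.11 and 0.06 within the numbers, adjusted p = 0.0364) and actin cytoskeleton and focal adhesion genes (-0.08, and -0.05 and -0.07 within the numbers, adjusted p = 0.0482). Each of them had an adjusted p = 0.954 with an estimated correlation, and none had a member passing without the replicate number. Leaving out 1 array gave 0 genes without any 1 of the 4 TGFbeta-treated arrays and 1 gene otherwise, 1 to 10 genes in the blocked fits, and 107 blocked without replicate 1 of the TGFbeta-treated major satellite cells. It gave 4 and 5 lists without a TGFbeta-treated control array, 0 and 2 without a TGFbeta-treated major satellite array, and 1 otherwise.

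Averaged over treatments, a comparison added after the data were seen, 2 genes differed between vectors, the probeset named Kcnma1 (-7.13, adjusted p = 0.000418) and Gm7982 (-2.76, adjusted p = 0.0363), both lower in major satellite cells. The 7 probesets of Gm7982 were all lower (-2.87 to -0.30), but with the mean of a gene's probesets it did not pass (-1.88, adjusted p = 0.117). The mean of the 2 probesets named Kcnma1 passed alone (-3.54, adjusted p = 0.00102), but only 1 of the 2 was lower (-7.13, the other 0.05), so it is no value of the gene. The blocked fit passed 17 genes, all lower. Unadjusted p was under 0.05 for 110 genes (blocked 1071), where 997 were expected by chance. Across genes, the average vector difference of replicate number 1 correlated with that of number 2 at r = 0.356 (0.117 by rank), and genes are not independent replicates. Without any 1 array, 1 or 2 genes passed and 8 to 19 did so blocked, except 49 blocked without replicate 1 of the TGFbeta-treated major satellite cells.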

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

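The tests of the probeset named Kcnma1 were chosen after the result was seen, as was the search of the probesets outside the gene comparisons. Of the 14823 probesets with several gene symbols or none, 1 differed between vectors without TGFbeta and 1 with TGFbeta, and both times it was a probeset without a gene name (probeset 10582549), which stood out as a signal in data outside the gene comparisons. It differed by -6.29 ± 0.30 without TGFbeta (adjusted p = 0.0324 over all probesets, blocked 0.00738), from a mean of 13.74 in control vector cells to 7.45 in major satellite cells. With TGFbeta it differed by -6.49 ± 0.30 (adjusted p = 0.022, blocked 0.00763), from 13.62 to 7.13. Array signal is compressed at both ends of the range, so these are differences of array values and not of transcript. With the replicate number in the model, 4 of these probesets passed without TGFbeta and 4 with it, all lower in major satellite cells. Averaged over treatments 2 passed (blocked 28), all lower.

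The unnamed probeset followed the probeset named Kcnma1 with 0 gene probesets between them in number, and both fell from close to the top of the range in all 4 control vector arrays. A change of the Kcnma1 gene itself as the cause needs a probeset that reads the gene. The changed probeset lists 0 of its RefSeq transcripts and has 0 of its 10 nearest gene probesets by number on the chromosome of Kcnma1. Of the 20625 probesets that list transcripts of their gene, 2.54% had 0 there, so the tables argue against it. The gene's other probeset lists 17 of the transcripts and has 10 of 10 neighbours there. It differed by 0.0476, but it lay near the floor in both lines (percentiles 9.65 and 10.1 of gene means) and could hardly fall, so whether the gene also changed stays open. In control vector cells its mean was 5.64 and that of the changed probeset 14.22, so it did not share the high value there. Gain or loss of the surrounding chromosome region would move the neighbours, and the 10 nearest gene probesets, all on 1 chromosome, had a median difference of -0.014, which argues against a change that spans them. What the probes read remains open, and so does whether the difference came with major satellite expression or with the derivation of each stably transfected line, which the design does not separate. A candidate explanation not tested is 1 transcript outside the named genes that both probesets read and that 1 line carried at a high level.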

How the results depend on the processing

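The average difference between vectors, the blocked fits without each array and the tests on probesets outside the gene comparisons were tests chosen after the result was seen. The replicate block (replicate number as a fixed term) kept every gene called without it and raised the counts of the TGFbeta comparisons to 2901, 3044 and, averaged, 4841, of the vector comparisons to 6, 6 and 17, of shared TGFbeta genes to 2229 and of lists between TGFbeta-treated lines to 4. It lost the BMP and Id list in control vector cells (adjusted p = 0.12), gained Notch and Wnt targets in major satellite cells (adjusted p = 0.517 with an estimated correlation) and changed no other list call in the TGFbeta comparisons. It left the difference of responses at 0 genes, and among 118 named gene results lost 0 of 79 calls and gained 10. As a random term it gave 2216 and 2298 TGFbeta genes, 3971 averaged, 4 and 5 between vectors, 16 averaged and 1745 shared. The higher counts came with a smaller residual spread, at a median SE of 0.0961 against 0.168.

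For the following the cause was not tested. Median centring gave 87 (57 higher) and 66 (36 higher) TGFbeta genes, 540 averaged and 61 shared. Quantile normalization again gave 108 (78 higher), 84 and 79 shared, and 1 and 3 lists between untreated and TGFbeta-treated lines. A trended and robust variance gave 124 in major satellite cells and 104 shared. The mean of probesets gave 1 gene, by the 2 probesets named Kcnma1 and without Gm7982, for the average vector difference. All probesets gave 0, 0, 462 averaged, 0 shared, and 2, 2 and, averaged, 3 between vectors. Adjusting their p over the genes alone gave 89, 39 and 620 TGFbeta genes, so the number of tests was part of it. By their construction, the groups of 1 comparison alone (fewer arrays) 0, 0 and 0 between untreated lines, an adjusted p threshold of 0.1 gave 432, 414 and 352 shared, and a 2-fold minimum 310 averaged.

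With an estimated correlation camera called 0, 0 and 0 lists in the TGFbeta comparisons and between TGFbeta-treated lines, and the size differences of -0.0453 (p = 0.181) and -0.0372 (p = 0.43) no longer passed. Fry, which compares a list with no other genes, gave in one direction 3, 3 and 0 lists. In either direction it gave 13 in major satellite cells and 0 between TGFbeta-treated lines. It called lists in control vector cells too (TGFbeta/Smad immediate targets, fry adjusted p = 0.000138). The difference of the genes that fell was -0.00205 with the fold minimum, no longer past the threshold, and turned to 0.0262 with genes selected in control vector cells alone (slope 0.96). With 500 genes selected in the other replicate number, the genes that rose gave -0.0129 in number 1 (slope 1.011) and those that fell -0.00642 in number 2 (slope 0.981).

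Leaving out 1 array leaves the replicate numbers unequal in the groups compared, and a lone array is assumed to vary like the other groups. It gave 0 to 89 and 0 to 82 TGFbeta genes, 359 to 638 averaged, 0 to 1 shared, 0 to 1 in each vector comparison, 1 to 2 averaged, and 0 to 0 for the difference of responses. Lists numbered 7 to 9 and 7 to 9 for TGFbeta, 0 to 7 and 0 to 5 between lines and 0 to 5 for the difference of responses. The size of the response ran from -0.132 to 0.0454 (rose), reversed only without replicate 1 of untreated major satellite cells, and from -0.168 to 0.109 (fell), reversed to 0.104, 0.109 and 0.0333, and the slope from 0.887 to 1.09. Blocked, the ranges were 1202 to 3161, 1228 to 3020, 2 to 9, 1 to 107, 0 to 17, 3498 to 4860 and 8 to 49, where 107, 17 and 49 came without replicate 1 of TGFbeta-treated major satellite cells. Of 1421 tested alternative values of the 79 named calls, 761 passed in the same direction, 660 no longer passed and 0 reversed. All 79 were lost in at least 1 alternative. Of 158 values within a replicate number, 0 had the opposite sign. That 0 was largely fixed in advance, since the calls used the same arrays and a gene with opposite signs could hardly pass. The rule of the same sign in both numbers removed none of the called genes. Detection of signal over background was not analysed here.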

Other observations

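The tests of the genes listed for their low values in major satellite cells and of the probesets without a gene were chosen after the result was seen, and the normalization test and the splits of the arrays were not. The following members of the fixed lists were chosen after their values were seen, and passed with the replicate number in the model and not without it. Ccl20, a chemokine of mucosal epithelia, changed by -3.53 after TGFbeta in control vector cells (adjusted p = 0.11, blocked 0.000174) and by -2.95 in major satellite cells (blocked 0.000468). Il33, which encodes the alarmin interleukin 33, changed by -2.61 (adjusted p = 0.164, blocked 1.04e-05) and by -2.24 (blocked 1.99e-05). Lmcd1, which encodes a LIM and cysteine-rich domain protein, was 2.47 higher (adjusted p = 0.185, blocked 0.000107) and 2.46 higher (blocked 0.000122), and Skil, a repressor of Smad signalling, 1.36 higher (blocked 3.83e-05) and 1.25 higher (blocked 5.49e-05). Uhrf1 and Hells, both known for the maintenance of DNA methylation, changed by -1.16 (blocked 0.00485) and -1.05 (blocked 0.000181) in control vector cells and by -1.07 (blocked 0.0069) and -1.08 (blocked 0.000176) in major satellite cells.

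Genes listed after their values were seen to be low in major satellite cells stand for no gene group, since the list was neither fixed before nor tested for enrichment. The median difference, major satellite minus control vector, was -2.34 for Zfp352, -1.20 for Tmem92, -1.14 for 5 Usp17l probesets, -0.62 for 3 Tcstv probesets and -0.55 for Ubtfl1. For the 9 Tdpoz and Spopfm probesets it was -0.54, and they ranged from -1.79 to 0.01. It was -0.30 for 5 Obox probesets, of which 1 names a single gene, and -1.94 for 3 Zscan4 and -1.74 for 2 Eif1a-like probesets, none of which names a single gene and which were outside the gene comparisons. Because the 9 families were picked for low values, it says nothing about probes shared between near-identical genes that 8 of them had a median below -0.5 and lay lower in each of the 4 comparisons within a replicate number, and shared probes stay open. Pluripotent cells mixed into the control vector cells would bring their own markers, and the 16 of 18 listed markers that were measured had a median difference of -0.00255 (SE 0.0191, from -0.198 for Pou5f1, at 6.38 in control vector and 6.18 in major satellite cells, to 0.12 for Fgf4), which argues against that source. Whether the differences came with major satellite or with the derivation of each line was not tested.

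The arrays of a replicate number deviated together. Between numbers 1 and 2, 10044 of 19937 genes differed, 3452 higher and 6592 lower in number 2, with a median absolute difference of 0.194. Lower lists in number 2 were DNA replication and G1/S (median -0.64, adjusted p = 1.21e-06), actin cytoskeleton and focal adhesion (-0.29, adjusted p = 0.00147), collagens and matrix crosslinking (-0.24, adjusted p = 0.0254), mitosis and G2/M (-0.28, adjusted p = 0.0365) and inflammatory cytokines and NF-kappaB (-0.28, adjusted p = 0.0365). With an estimated correlation none of the 5 passed (adjusted p = 0.723 for mitosis and G2/M and 0.619 for each other). The calls hold only in camera's preset setting, which differs from the other in degrees of freedom as well as in correlation. Quantile normalization left 146% of the difference of gene probesets. It gives all arrays a common distribution and cannot remove offsets that differ from probeset to probeset. The median signed difference was -0.0798 for gene probesets and 0.169 for those outside the probe table. These opposite signs argue against a single shift of all probesets as the only cause. Whether the numbers were normalized apart cannot be decided by this test. Probesets outside the probe table had a median absolute difference of 0.362, 1.87 times that of gene probesets. A difference in labelling or hybridization that also moves probesets without a gene would give a ratio of 1 or above. The 2 sets were not matched for signal level, and other causes could give such a ratio too. Labelling, hybridization, cultures, days and separate normalization of the numbers therefore all stay open.

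The 8 arrays were split into 4 and 4 in all 35 ways, each fitted with 2 group means. TGFbeta against untreated called 1719 genes, and the highest of the other splits, replicate number 1 against 2, called 6941. Thus 2 of the 35 splits, the real one included, called as many, so chance cannot be excluded by this count alone. The split with more calls follows the shared title code and points to a structure of the samples, and the fit with the replicate number called 4841 genes for TGFbeta. Major satellite against control vector called 3 genes, and every remaining split 0.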
